A study of Mus musculus with 3 samples.

How the data were processed

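Messenger RNA was measured in 3 mouse tumour cell lines by RNA sequencing, with 1 library per line. Per the labels' protocols, total RNA was extracted from frozen cell pellets, treated with DNase, enriched for polyadenylated RNA with oligo(dT), fragmented, copied into cDNA and amplified by PCR. The libraries were sequenced on an Illumina instrument by the company BGI, which also filtered the reads and processed them, per the design text of the series. The submitters' processing notes name HISAT and StringTie, with no versions, and the mouse genome build mm10. The program that made the counts is not given in the sources used here.

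The deposited tables hold 1 row per gene, with an expected count (an estimated number of reads, which need not be whole), an FPKM value, a length and text descriptions of the gene, per the file headers. The authors' expected counts are not normalised, and between 88.1% and 88.9% of them are whole numbers (within 0.005 of one). The authors' FPKM values are per kilobase of transcript and scaled to the total expected count of the same table. This was checked from the values: the library total implied by the FPKM, the count and the length of genes with over 500 counts was between 0.980 and 0.987 of the table's own total, so the length used was close to the listed length. The gene models are RefSeq messenger RNAs together with transcripts that the authors assembled from reads, and no noncoding RefSeq record and no mitochondrially encoded gene is listed.

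The assembled transcripts differ between tables. The B16-F1 and Cloudman S91 tables share 1 set: all 4906 assembled transcript names that both list belong to the same gene. The 4T1 table has another set, in which only 2 of the 4105 names it shares with B16-F1 belong to the same gene, so an assembled transcript cannot be followed from the melanoma tables into the 4T1 table. Of the 15529 genes with a symbol in any table, 4165 have an assembled transcript in at least 1 table. The listed length differs by over 20% (a ratio above 1.2) for 198 named genes between the melanoma tables, and for 716 between B16-F1 and 4T1. Rows with no symbol were left out of all comparisons. They held 2.36% of the expected counts in B16-F1, 2.24% in Cloudman S91 and 4.32% in 4T1.

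No table has a row at 0, and the smallest expected count listed was 0.11, 0.17 and 0.18 in the order B16-F1, Cloudman S91, 4T1. A gene that a table does not list was therefore taken as 0. The total expected count was 9098072 in B16-F1, 7412840 in Cloudman S91 and 8968897 in 4T1. Intervals beside single values are exact 95% intervals from the rounded expected counts (Poisson for 1 library, conditional binomial for a ratio of 2 libraries, scaled to the FPKM ratio), and Wilson intervals were used for shares. They cover counting error only, and PCR copies make reads less independent than they assume. Against a library that does not list a gene, a fold is a lower bound, computed with 3 counts in that library and written "at least".

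With 1 library per line there is no spread between replicates, so no test, p-value or standard error across genes was computed. Genes were called by a fixed rule of size: a difference of at least 2 in log2(FPKM + 1), which is 4-fold on that scale, among genes at FPKM 1 or more in at least 1 of the lines compared. Differences on this scale understate the folds of low genes. Correlations are across genes, which are not independent replicates. The rule, 36 gene lists (9 of them for other cell types or RNA quality; 540 genes in all, of which 490 are in a table) and the alternatives were fixed before the data were examined. For each list with at least 5 members at FPKM 1 or more, the median difference was placed among the medians of 10000 random lists of the same size, matched on mean expression in 20 bins. A list was called outside when its percentile was below 2.5 or above 97.5, as 5% of random lists are. This describes the libraries and is not a test of the lines.

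Named genes follow a rule fixed at the same time: per pair of lines the 10 genes with the largest difference in each direction among those at FPKM 10 or more, leaving out symbols of predicted or unnamed genes. A gene that this rule selects is not reported here. The rule adds the 2 to 4 members of a described list with the largest differences, the 5 genes with the highest FPKM in each line, and fixed genes of the sex chromosomes and of known strain or tumour genotypes. Positions are from RefSeq GRCm38.p6, whose primary sequence is that of mm10, matched by Entrez gene number for 15500 of the 15529 named genes, and they span the whole gene.

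The alternatives were other pseudocounts (0.1 and 5), no filter or an FPKM minimum of 5, rescaling to TPM with and without the 50 most abundant genes, median-of-ratios and upper-quartile scaling, only plain gene symbols, expected counts scaled to the library total, 2-fold and 8-fold rules, unmatched random lists, list means, and the mean of the melanoma lines against 4T1. A further 3 were added after seeing the data: only genes with no assembled transcript, only genes listed in all 3 tables, and unnamed assembled genes added to the named gene with the same protein description. The last was chosen after the low Gapdh value of 4T1 had been seen. The calculation was tested on simulated counts for the comparison of B16-F1 with Cloudman S91 over 10890 genes. All 100 genes changed 8-fold and all 100 changed 16-fold passed the size rule, and 0 of 10670 unchanged genes did. The simulated counts had Poisson noise only, and changed genes were drawn from those at a mean FPKM of 10 or more. The changes were well past the 4-fold rule, so this checks the calculation and not its error rate in real libraries. A simulated list of 20 genes raised 2-fold had a median of 0.92 and lay above all random lists, and 1 of 60 unshifted lists was outside. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots used matplotlib 3.10.9.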

Results

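The messenger RNA of 3 mouse tumour cell lines was profiled, with 1 library per line. B16-F1 is a skin melanoma line from C57BL/6J mice, Cloudman S91 is a skin melanoma line from DBA mice, and 4T1 is a mammary carcinoma line from BALB/cfC3H mice. Both melanoma lines were grown in DMEM and 4T1 in RPMI, each with serum, so tumour type, strain and medium differ together between 4T1 and the others. The tables summed to 9098072 expected counts for B16-F1, 7412840 for Cloudman S91 and 8968897 for 4T1, and listed 13606, 13884 and 13188 named genes. Of these, 10466, 10527 and 10564 reached FPKM 1. There were no replicates, so every difference given here is between libraries, has no replicate check, and carries counting error only. The median over all genes lay at 0.14 for B16-F1 minus Cloudman S91, 0.03 for B16-F1 minus 4T1 and -0.14 for Cloudman S91 minus 4T1 in log2(FPKM + 1), and the matched random lists carry the same shifts. Rescaling to TPM moved these medians to 0.06, 0.38 and 0.31.

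The melanoma libraries were closest to each other. Across the 11944 genes at FPKM 1 or more in at least 1 line, Pearson's r of log2(FPKM + 1) was 0.880 between B16-F1 and Cloudman S91 (Spearman's rho 0.882), 0.711 between B16-F1 and 4T1 (rho 0.709) and 0.672 between Cloudman S91 and 4T1 (rho 0.673). Leaving out predicted and unnamed genes, the 5 most abundant genes of B16-F1 were Ftl1 (ferritin light chain, FPKM 4936), Eef1a1 (a translation elongation factor, 4811), Gapdh (a glycolytic enzyme, 4591), Ppia (cyclophilin A, 3643) and Dct (dopachrome tautomerase of the melanin pathway, 3007). In 4T1 they were Rps12 (5902), Lgals1 (galectin-1, 5860), Eef1a1 (5504), Rplp1 (5072) and Rps18 (4478), of which Rps12, Rplp1 and Rps18 encode ribosomal proteins. In Cloudman S91 they were Prnp (the prion protein, 14280), Slc38a6 (4929), Adamts13 (4618), Eef1a1 (3690) and Sectm1a (3584), and the predicted gene Gm13710 (15425) was higher than any of them. Prnp alone held 5.26% of that library's counts, against 0.509% in B16-F1 and 0.512% in 4T1. In Cloudman S91 the counts of Prnp, Slc38a6, Adamts13 and Sectm1a were not whole numbers, and their levels are uncertain. This trait does not single them out. The count of Eef1a1 was not whole either. Outside the abundant genes highest in this line, 21 of 36 genes at FPKM 1000 or more had such counts.

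The comparison of B16-F1 with 4T1 sets a melanoma line beside a mammary carcinoma line. Genes of melanin synthesis were among the most abundant of B16-F1, and 8 of the 19 pigment genes were not listed in 4T1. Dct (chromosome 14, 118012790 to 118052246) had FPKM 3007 in B16-F1, at least 20017-fold above 4T1. Tyrp1, another enzyme of the pathway (chromosome 4, 80834123 to 80851736), had 2901, at least 23367-fold higher, and Pmel, which forms the fibrils of the melanosome, had 2676 against 0.11 (2 counts), a ratio of 24331 with a counting interval of 6735 to 200912. Mlana, a melanosome protein, had 1186 and was at least 2281-fold higher. In the other direction, the simple epithelial keratins Krt18 (752 in 4T1 against 0.08), Krt8 (403, not listed in B16-F1) and Krt7 (401 against 0.07) separated the libraries, with Krt8 at least 2123-fold higher in 4T1.

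By the size rule 729 genes were higher in B16-F1 and 858 were higher in 4T1, of 11547 compared, so 45.9% of the calls were higher in B16-F1. Under TPM the counts were 1188 and 909 (56.7%), so which line had more calls depended on the scaling. Of the gene lists with enough measured members, 20 of 27 lay outside the range of random lists, with 1.35 expected at random. Some lists share members, such as Fosl1, Axl and Atf3, and genes of a list can change together. The expected number, here and in the other comparisons, holds for random lists of unrelated genes. All 19 genes of the pigment production list were measured, and 18 were over 4-fold higher in B16-F1 (median difference 5.20, or 5.06 with genes not listed in 4T1 set at 3 counts), above all 10000 random lists. Among the melanocyte and neural crest regulators 9 of 11 were higher in B16-F1 (median 3.40, above all random lists). They included the transcription factors Sox10 (204, not listed in 4T1), Mitf (133 against 1.23) and Pax3 (49.6, not listed in 4T1). Further genes with the largest excess in B16-F1 were Slc45a2 (307), a melanosome transporter, Rab38 (199), a GTPase of melanosome biogenesis, Syt4 (194), a synaptotagmin, and Sectm1a (756, an uncertain level), all not listed in 4T1, and Ptgds, a prostaglandin D synthase (421 against 0.60). The Schwann cell and neural markers were higher in B16-F1 for 4 of 8 members (median 1.66, percentile 99.98), led by the neuronal tubulin Tubb3 (108 against 0.72) and the myelin gene Mbp (50.02 against 6.84, a ratio of 7.31, or 3.34 in scaled counts, since its listed lengths differ).

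The epithelial junction and keratin list lay below all random lists, with 20 of 22 measured genes over 4-fold higher in 4T1 (median -5.10, or -4.93 with unlisted genes at 3 counts). Beside the keratins it included the tight junction gene Cldn3 (216, not listed in B16-F1). Mammary luminal and basal markers were higher in 4T1 for 4 of 7 members (median -4.17), among them Cd24a (105 against 1.24), the luminal transcription factor Gata3 (23.2 against 0.07) and Krt14 (20.7 against 0.15), a basal keratin that is also 1 of the keratinocyte markers. Of the 18 genes on this mammary list, 14 were in any table and only 7 reached FPKM 1 in 4T1, where the median of the 14 was 1.03. Other genes with the largest excess in 4T1 were Wfdc2 (730), Anxa3, an annexin (545), and Spint2, a protease inhibitor (280), none listed in B16-F1, and S100a6, a calcium-binding protein (3849 against 4.82). Eno1b (621, not listed in B16-F1) is near-identical to Eno1 and can share reads with it. With the copies added together, enolase was 2072 in 4T1 against 1841 in B16-F1, so the excess of Eno1b was not seen in the sum.

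Of 16 genes of MHC class I antigen presentation, 11 were over 4-fold higher in 4T1 (median -2.47, below all random lists), with the immunoproteasome subunit Psmb8 (69.3) not listed in B16-F1, the class I heavy chain H2-K1 at 318 against 10.3, and the peptide transporter Tap2 at 50.9 against 0.86. H2-L (370, not listed in B16-F1) was among the genes with the largest difference. It is present in only some mouse strains and shares sequence with H2-D1. The chemokine and cytokine list had 13 of 19 genes higher in 4T1 (median -3.76, or -3.52 with unlisted genes at 3 counts), among them the colony-stimulating factors Csf3 (84.2, not listed in B16-F1) and Csf1 (132 against 2.89) and the chemokines Cxcl16 (89.4 against 0.09) and Cxcl1 (77.8, not listed in B16-F1). Interferon-stimulated genes were higher for 6 of 25 members (median -0.98, percentile 0.13), led by Oasl1 (25.0 against 0.11) and Isg15 (59.0 against 2.52). The proteases and invasion list had 9 of 16 genes higher in 4T1 (median -2.65), among them Spp1 (161 against 0.24) and the matrix metalloproteinase Mmp3 (31.5, not listed in B16-F1), and Timp3 higher in B16-F1 (6.49, not listed in 4T1).

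Further lists differed between B16-F1 and 4T1. The dedifferentiated melanoma list had 10 of 12 genes higher in 4T1 (median -3.72), with Ankrd1 (233), Fosl1 (199) and the receptor kinase Axl (212 against 0.97) among them, and Ankrd1 and Fosl1 not listed in B16-F1. The mesenchymal list was lower in B16-F1 (median -1.92, percentile 0.02), with 6 of 12 genes higher in 4T1, such as S100a4 (510 against 3.86), and 2 higher in B16-F1, among them the cadherin Cdh2 (23.3, not listed in 4T1). MAPK pathway output was over 4-fold higher in 4T1 for 4 of 15 genes (median -1.06, percentile 0.03), with Fosl1 and Etv4 (30.3 against 0.48) at the top, and for Dusp4 in B16-F1 (71.0 against 14.7). The unfolded protein and integrated stress list (median -1.14, percentile 0.03) had 4 of 16 genes higher in 4T1, led by Atf3 (87.1 against 4.85) and Trib3 (199 against 13.4), and Sdf2l1 higher in B16-F1 (63.7 against 14.8). Checkpoint and immune ligands had 5 of 11 genes higher in 4T1 (median -1.85, percentile 0.03), led by the ectonucleotidase Nt5e (54.1, not listed in B16-F1) and the death receptor Fas (8.68 against 0.22), and Lgals9 higher in B16-F1 (60.9 against 13.1). The NRF2 target list lay higher in B16-F1 (median 1.05, percentile 99.93), with the glutathione transferases Gsta1 (63.8 against 0.70) and Gstm1 (48.2 against 1.61) over 4-fold higher. Cell cycle genes lay higher in B16-F1 (median 0.61, percentile 99.90), although only Ccne1 (23.1 against 3.65) and Rrm2 (197 against 44.9) passed 4-fold and the cyclin Ccnd1 was higher in 4T1 (300.1 against 57.6).

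Lysosomal genes (median 0.57, percentile 99.41) and glycolysis (median 0.53, percentile 99.31) were the other lists above the range in B16-F1. Of the 19 lysosomal genes 2 were over 4-fold higher in B16-F1, led by Hexa (186 against 10.7), and 2 in 4T1, led by Ctsh (48.8 against 3.0). The glycolysis list was led by Gapdh (4591 against 45.8) and Slc16a3 (43.3 against 0.10). The Gapdh level is uncertain, since assembled genes without a symbol that are described as this enzyme held FPKM 6515 in 4T1 and 5489 in B16-F1. The sums were 10080 in B16-F1 and 6561 in 4T1. Receptor tyrosine kinases (median -0.66, percentile 2.31), with Axl and Epha2 (108 against 0.20) over 4-fold higher in 4T1 and 3 genes, led by Met (165 against 11.2), in B16-F1, and immediate early and heat shock genes (median -0.85, percentile 1.43), with Junb (208 against 8.86) and Atf3 higher in 4T1, completed the lists outside. The kinase call was lost in 6 alternatives, and in 1 more the list passed the middle of the random lists. The calls of immediate early genes, lysosome, glycolysis, checkpoint ligands and the mesenchymal list were lost in 3, 2, 2, 1 and 1. The lists for cytosolic nucleic acid sensing (median -0.40), p53 targets (0.17), tumour suppressors (0.13), Wnt targets (-0.29), hypoxia (-0.56), oxidative phosphorylation (0.06) and cholesterol synthesis (0.36) lay inside the range.

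**Figure D1:**
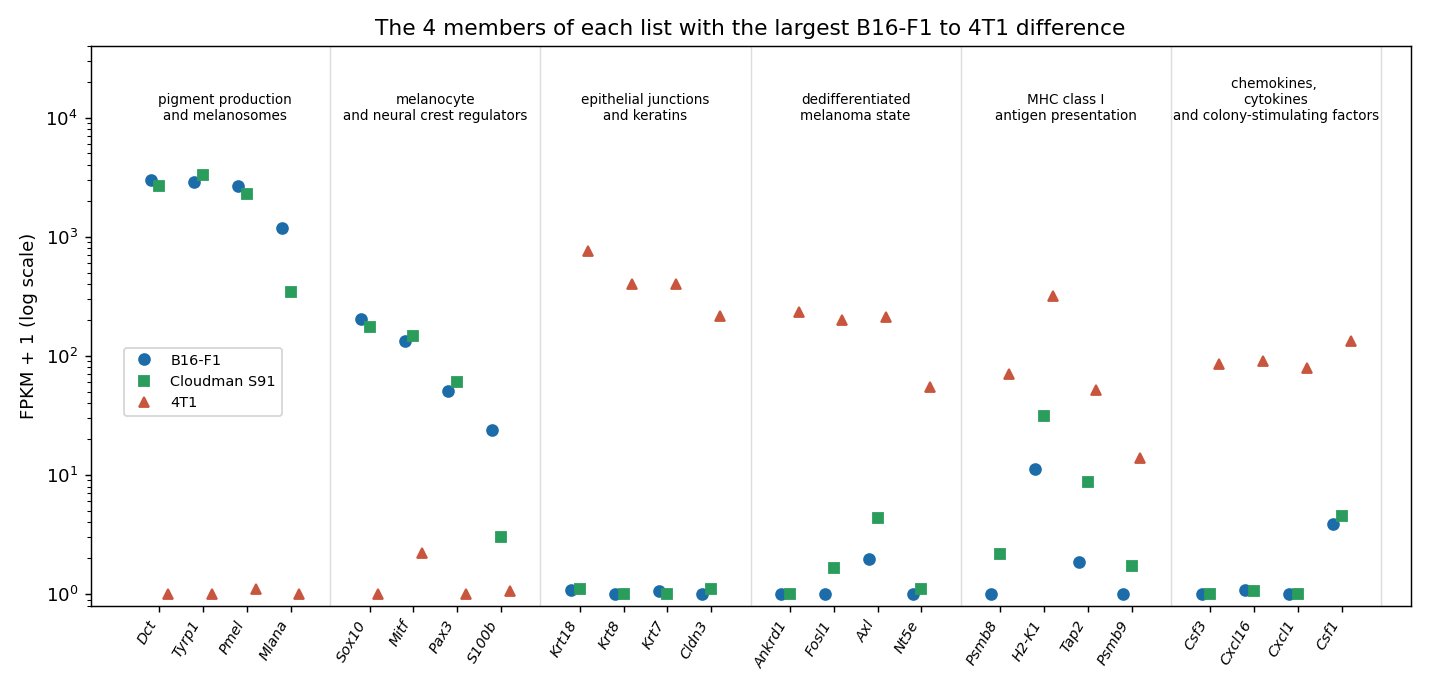
FPKM + 1 on a log axis in the 3 libraries, 1 point per library, for the 4 members of 6 gene lists with the largest difference between B16-F1 and 4T1. Both melanoma libraries lie together above 4T1 for pigment genes (Dct 3007 and 2683 against a gene not listed) and below it for keratins (Krt18 0.08 and 0.10 against 752).

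The comparison of Cloudman S91 with 4T1 sets the other melanoma line beside the mammary line. Dct, Tyrp1, Pmel and the keratins Krt18, Krt8 and Krt7 were again among the 10 largest differences. Tyrp1 had FPKM 3290 in Cloudman S91, at least 26506-fold above 4T1, and Dct had 2683, at least 17868-fold higher. Pmel had 2291 against 0.11, a ratio of 20832 with a counting interval of 5766 to 172020, and Oca2, a melanosome channel protein, had 479, at least 10731-fold higher. Krt18 (752 in 4T1 against 0.10), Krt8 (403) and Krt7 (401) were on the side of 4T1, the latter pair not listed in Cloudman S91.

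By the size rule 871 genes were higher in Cloudman S91 and 934 in 4T1, of 11657 compared (48.3% of calls higher in Cloudman S91), and under TPM 1414 and 945 (59.9%). In all, 15 of 28 lists lay outside the range of random lists, with 1.40 expected for lists of unrelated genes. The pigment list was higher in Cloudman S91 for 17 of 19 genes and in 4T1 for Slc7a11 (median 5.20, or 5.08 with unlisted genes at 3 counts) and the melanocyte regulators for 9 of 13 (median 3.45, or 3.26 at 3 counts), both above all random lists. Sox10 had 175, Mitf 144 against 1.23, and Pax3 59.9, with Sox10 and Pax3 not listed in 4T1. Other genes with the largest excess in Cloudman S91 were Mlana (344), Syt4 (287) and Tcl1, a cofactor of AKT kinases (377), none listed in 4T1, and, at uncertain levels, Sectm1a (3584), Slc38a6 (4929 against 1.77, a ratio of 2785, or 914 in scaled counts) and Adamts13 (4618 against 9.40). Schwann cell and neural markers were higher for 3 of 7 (median 1.56, percentile 99.73), again with Tubb3 (32.8 against 0.72) and Mbp (98.2 against 6.84, a ratio of 14.4, or 6.78 in scaled counts).

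Epithelial genes were higher in 4T1 for 20 of 22 members (median -4.45), mammary markers for 4 of 8 (median -2.78, or -2.43 with unlisted genes at 3 counts) and the dedifferentiated melanoma list for 8 of 13 (median -3.15), each below all random lists. Pgr, the progesterone receptor on the mammary list, went the other way (8.17 in Cloudman S91, not listed in 4T1). Further genes at the top for 4T1 were Wfdc2 (730), Anxa3 (545), the integrin Itga3 (269), Ankrd1 (233), Igfbp7 (207) and Cldn3 (216 against 0.11), of which only Cldn3 was listed in Cloudman S91. Rpl3, a ribosomal protein gene, was also among them (1575 against 5.17), but an assembled gene with the same description held 924 in Cloudman S91, and the sums were 1589 and 930.

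MHC class I genes were over 4-fold higher in 4T1 for 9 of 16 members (median -2.21) and chemokines and cytokines for 13 of 19 (median -3.76, or -3.42 with unlisted genes at 3 counts), both below all random lists. Psmb8 had 69.3 against 1.15 and the class I regulator Nlrc5 13.6 against 0.43, while Cxcl16 had 89.4 against 0.06 and Csf3 (84.2) and Cxcl1 (77.8) were not listed in Cloudman S91. Interferon-stimulated genes (9 of 25 higher in 4T1, median -0.91, percentile 0.76) were led by Oasl1 (25.0 against 0.26) and Oasl2 (20.1 against 0.13). The proteases list (8 of 16 higher in 4T1, 3 in Cloudman S91, median -2.28) had Spp1 (161 against 1.08) on the side of 4T1 and the gelatinase Mmp2 (120 against 0.11) and the protease inhibitor Timp3 (61.7, not listed in 4T1) on that of Cloudman S91. Hypoxia genes lay lower in Cloudman S91 (median -0.99, percentile 1.08), led by Egln3 (15.4 in 4T1, not listed in Cloudman S91) and Ndrg1 (143 against 7.88), as did the unfolded protein list (median -1.23, percentile 0.18), led by Atf3 (87.1 against 2.80). Lists above the range in Cloudman S91 were p53 targets (median 0.74, percentile 99.57), with Trp53inp1 (14.96 against 1.71) higher and Perp (61.1 against 0.15) lower, lysosome (0.67, percentile 99.97), with the cathepsin Ctsk (22.8 against 0.37) higher and Ctsh (48.8, not listed in Cloudman S91) lower, and cholesterol synthesis (0.43, percentile 98.95), led by Idi1 (50.3 against 11.7). The cholesterol call was lost in 3 alternatives, and those of lysosome, p53 targets and the unfolded protein list in 1 each.

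The remaining lists lay inside the range in this comparison, among them the mesenchymal list (median -0.03), in which Fbn1 (13.9 against 0.03) and Cdh2 (30.8, not listed in 4T1) were higher in Cloudman S91 and S100a4 (510 against 8.28) in 4T1. Medians were -0.70 for cytosolic nucleic acid sensing, -0.48 for checkpoint ligands, -0.47 for the cell cycle, 0.11 for receptor tyrosine kinases, 0.11 for tumour suppressors, 0.28 for MAPK output, -0.27 for Wnt targets, -0.33 for glycolysis, -0.10 for oxidative phosphorylation, 0.38 for NRF2 targets, 1.49 for fibroblast markers and -0.85 for immediate early genes. Slc7a11, the cystine transporter among the NRF2 targets, was higher in 4T1 (42.1 against 2.89). The Gapdh difference (1390 against 45.8) turned when assembled genes with the same description were added (3012 against 6561).

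Genes that differed from 4T1 in the same direction in both melanoma lines numbered 459 higher and 665 lower in melanoma. The first group held the pigment genes Dct, Tyrp1, Pmel, Mlana, Slc45a2 and Oca2 and the regulators Sox10, Mitf and Pax3. The second held Krt18, Krt8, Krt7, Wfdc2, Anxa3, S100a6 (61.1 in Cloudman S91), Ankrd1 and Axl. Among 11260 genes compared in both, independent lists of the same sizes would share 40.1 and 71.2 genes. When all 3 libraries were simulated from the 4T1 counts with no change, the overlaps were 0 in either direction with Poisson noise. With an assumed coefficient of variation of 0.4 they were 12.6 and 2.25. A gene not listed in 4T1, such as Dct or Sox10, stayed at 0 in every simulated library and could not count as higher in melanoma. At FPKM 1 or more, 388 such genes were in B16-F1 and 451 in Cloudman S91. The simulated overlaps are thus no fair reference for the 459. The 4T1 library was shared and could not be split, so part of the excess over independent lists may come from it.

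B16-F1 and Cloudman S91 are both melanoma lines from different strains, in the same medium, with the same gene models. The medians of the cell cycle, glycolysis, NRF2 target and hypoxia lists lay above the range of random lists, and those of the mesenchymal and MAPK output lists lay under it, though most of their members were less than 4-fold apart. All 20 cell cycle genes were under 4-fold apart, yet the list's median was 1.06 (above all random lists), led by the replication gene Mcm2 (188 against 60.1) and the mitotic cyclin Ccnb1 (117 against 44.1). Glycolysis had a median of 1.01 (above all random lists), led by Eno1 (1841 against 139), Pkm (1498 against 448) and Gapdh (4591 against 1390). With enolase copies added, the values were 1841 and 350.1, and with Gapdh copies 10080 and 3012. MAPK output was lower in B16-F1 (median -0.75, percentile 0.02), with the ETS factors Etv4 (0.48 against 17.8) and Etv5 (2.28 against 37.1) and the pathway inhibitors Dusp6 (23.7 against 126) and Spry4 (0.41 against 7.94) over 4-fold higher in Cloudman S91.

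By the size rule 259 genes were higher in B16-F1 and 355 in Cloudman S91, of 11133 compared. The counts were 387 and 527 under TPM, and 387 and 625 under TPM without the 50 most abundant genes. In all, 14 of 26 lists lay outside the range, with 1.30 expected for lists of unrelated genes. Among the NRF2 targets (median 0.79, percentile 99.81) Gsta1 (63.8 against 2.32) and Gstm1 (48.2 against 10.96) were over 4-fold higher in B16-F1, and among hypoxia genes (median 0.70, percentile 99.24) Pdk1 (11.8 against 0.10) and Bnip3 (48.7 against 10.5). The mesenchymal list was lower in B16-F1 (median -0.83, percentile 0.32), led by the matrix gene Fbn1 (0.10 against 13.9) and Tagln (0.29 against 7.92). These 6 lists kept their call in all alternatives that gave a value.

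Other lists were lower in B16-F1 with less stable calls. Receptor tyrosine kinases (median -0.75, percentile 0.09) were led by Pdgfra (0.17 against 15.6) and Kit (3.73 against 35.6), with Met higher in B16-F1 (165 against 31.4). MHC class I genes (median -0.42, percentile 0.22) were led by Tap2 (0.86 against 7.80) and H2-K1 (10.3 against 30.5), and p53 targets (median -0.50, percentile 0.03) by Eda2r (2.81 in Cloudman S91, not listed in B16-F1) and Trp53inp1 (6.68 against 14.96). Wnt targets (median -1.44, percentile 0.06, 6 genes) were led by Nkd1 (0.11 against 3.76), with Znrf3 higher in B16-F1 (3.35 against 0.04). The unfolded protein list (median -0.23, percentile 0.26) was led by Trib3 (13.4 against 28.5), and the melanocyte regulators (median -0.27, percentile 1.35) by Foxd3 (9.93 in Cloudman S91, not listed in B16-F1), with S100b higher in B16-F1 (23.0 against 2.0). Proteases (median -0.45, percentile 1.58) were led by Mmp2 (1.71 against 120) and Timp3 (6.49 against 61.7), and checkpoint ligands (median -0.63, percentile 1.70) by Cd200 (0.24 against 47.1). The protease call was lost in 7 alternatives, melanocyte regulators in 4, checkpoint ligands in 3, Wnt targets and the unfolded protein list in 2 each, and the kinase, MHC class I and p53 lists in 1 each. In 3 more alternatives the checkpoint ligands passed the middle of the random lists.

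Pigment genes as a group lay inside the range (median 0.50, percentile 92.15), but Tyr, the tyrosinase that starts melanin synthesis (chromosome 7, 87424771 to 87493512), was the 1 member over 4-fold apart. It had FPKM 102 (95% counting interval 99.1 to 104) in B16-F1 against 4.99 (4.36 to 5.70) in Cloudman S91, a ratio of 20.4 (17.8 to 23.4). In the mammary line 4T1 it had 5.74 (5.10 to 6.42). The ratio of Cloudman S91 to 4T1 was 0.869 (0.727 to 1.04), so these libraries did not differ beyond counting error, the only error this interval covers. Tyr counts were not whole numbers in any of the 3 libraries. The other lists inside the range were dedifferentiated melanoma (median -0.45), interferon-stimulated genes (0.02), nucleic acid sensing (0.31), chemokines (-0.09), tumour suppressors (-0.02), oxidative phosphorylation (0.21), lysosome (0.11), cholesterol synthesis (-0.04), fibroblast (-0.74), Schwann cell and neural markers (0.23) and immediate early genes (-0.14).

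The largest single differences in favour of B16-F1 were Plagl1, an imprinted zinc finger gene (118 against 0.67, a ratio of 176 with an interval of 120 to 270), the cyclophilin Ppic (82.1 against 0.55), Gsdmc, a gasdermin (51.7), Nrp2, a neuropilin receptor (63.3 against 0.26), Fkbp6 (112 against 1.94) and Foxr2 (32.7), with Gsdmc and Foxr2 not listed in Cloudman S91. Rpl3 (841 against 5.17) led the 10, but its sum with an assembled gene of the same description was 842 against 930. The other 3 of the 10 lie near each other on chromosome 6. Sgce (4674350 to 4747204) had 44.6 against 0.24, Pon2 (5264620 to 5298345) had 39.6 against 0.08, and Slc25a13 (6041218 to 6217304) had 37.3 and was not listed in Cloudman S91, at least 284-fold lower there.

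**Figure D2:**
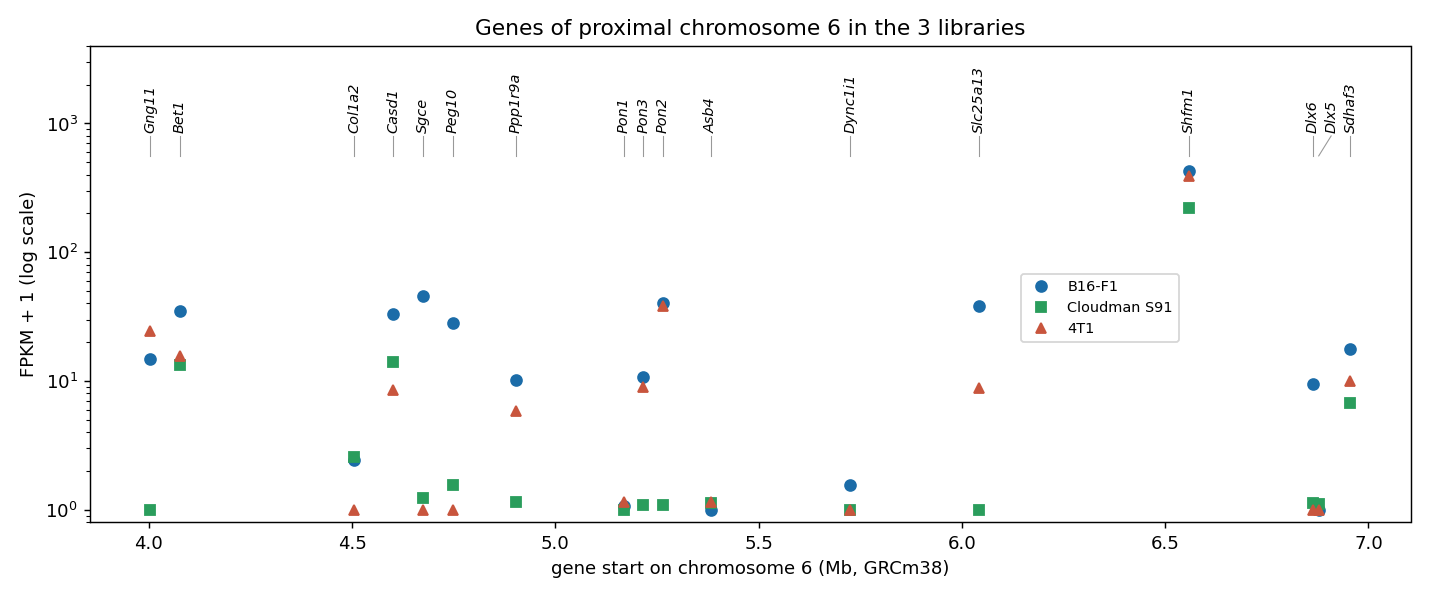
FPKM + 1 on a log axis against gene start on chromosome 6 (GRCm38, Mb), 1 point per gene and library, with the region and its genes chosen after the values were seen. In Cloudman S91, Pon2 (0.08) and Slc25a13 (not listed) lie at the floor, while B16-F1 has 39.6 and 37.3 and 4T1 has 36.9 and 7.89.

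The largest differences in favour of Cloudman S91 were Tcl1 (377 against 0.46, a ratio of 820 with a lower bound of 505, or 437 in scaled counts), Fcgr2b, an inhibitory Fc receptor (166 against 0.24), Dpep3 (87.9), Fcer1g, the common Fc receptor gamma chain (122 against 1.05), the protocadherin Pcdhgc3 (64.9 against 0.17), the receptor Mrgpra4 (51.6) and the homeobox gene Rhox2h (50.4). Dpep3, Mrgpra4 and Rhox2h were not listed in B16-F1, nor were H2-L (52.0) and Eno1b (91.4). The Pcdhgc3 gene shares exons with its cluster, and its level is uncertain.

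Among genes highest in 1 line, 114 were highest in B16-F1, such as Tyr, Plagl1, Ppic and Gsdmc, 256 in Cloudman S91, such as Tcl1, Fcgr2b, Fcer1g and Prnp, and 665 in 4T1, such as Krt18 and Wfdc2. Over genes with no assembled transcript in any table, chosen after seeing the data, the numbers were 67, 164 and 429.

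Fixed genotype genes differed as follows. Cdkn2a, which encodes the tumour suppressors p16 and p19 (chromosome 4, 89274473 to 89294619), was listed only in Cloudman S91, at 29.0 (187 counts, interval 25.0 to 33.5), at least 76.5-fold above B16-F1 and at least 75.4-fold above 4T1. Trp53 had 77.7, 48.1 and 88.9 in the order B16-F1, Cloudman S91, 4T1, and Myo5a, the dilute coat colour gene, 91.4, 64.3 and 11.7. The listed length of Myo5a differed between the tables (11622, 5665 and 11718 bases), and its ratio of B16-F1 to Cloudman S91 was 1.42 in FPKM but 2.93 in counts scaled to the library total. Nnt, which is deleted in part in C57BL/6J mice, had 32.5 in B16-F1 against 17.6 and 17.9 in the others. Ahr had 3.27, 16.6 and 2.15. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty had at most 8 counts in any library and were not listed in 4T1, and Xist, Cd5l and Nlrp1b were in no table. Xist makes a noncoding RNA, and no noncoding RefSeq record is listed, so its absence says nothing about its level.

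**Figure D3:**
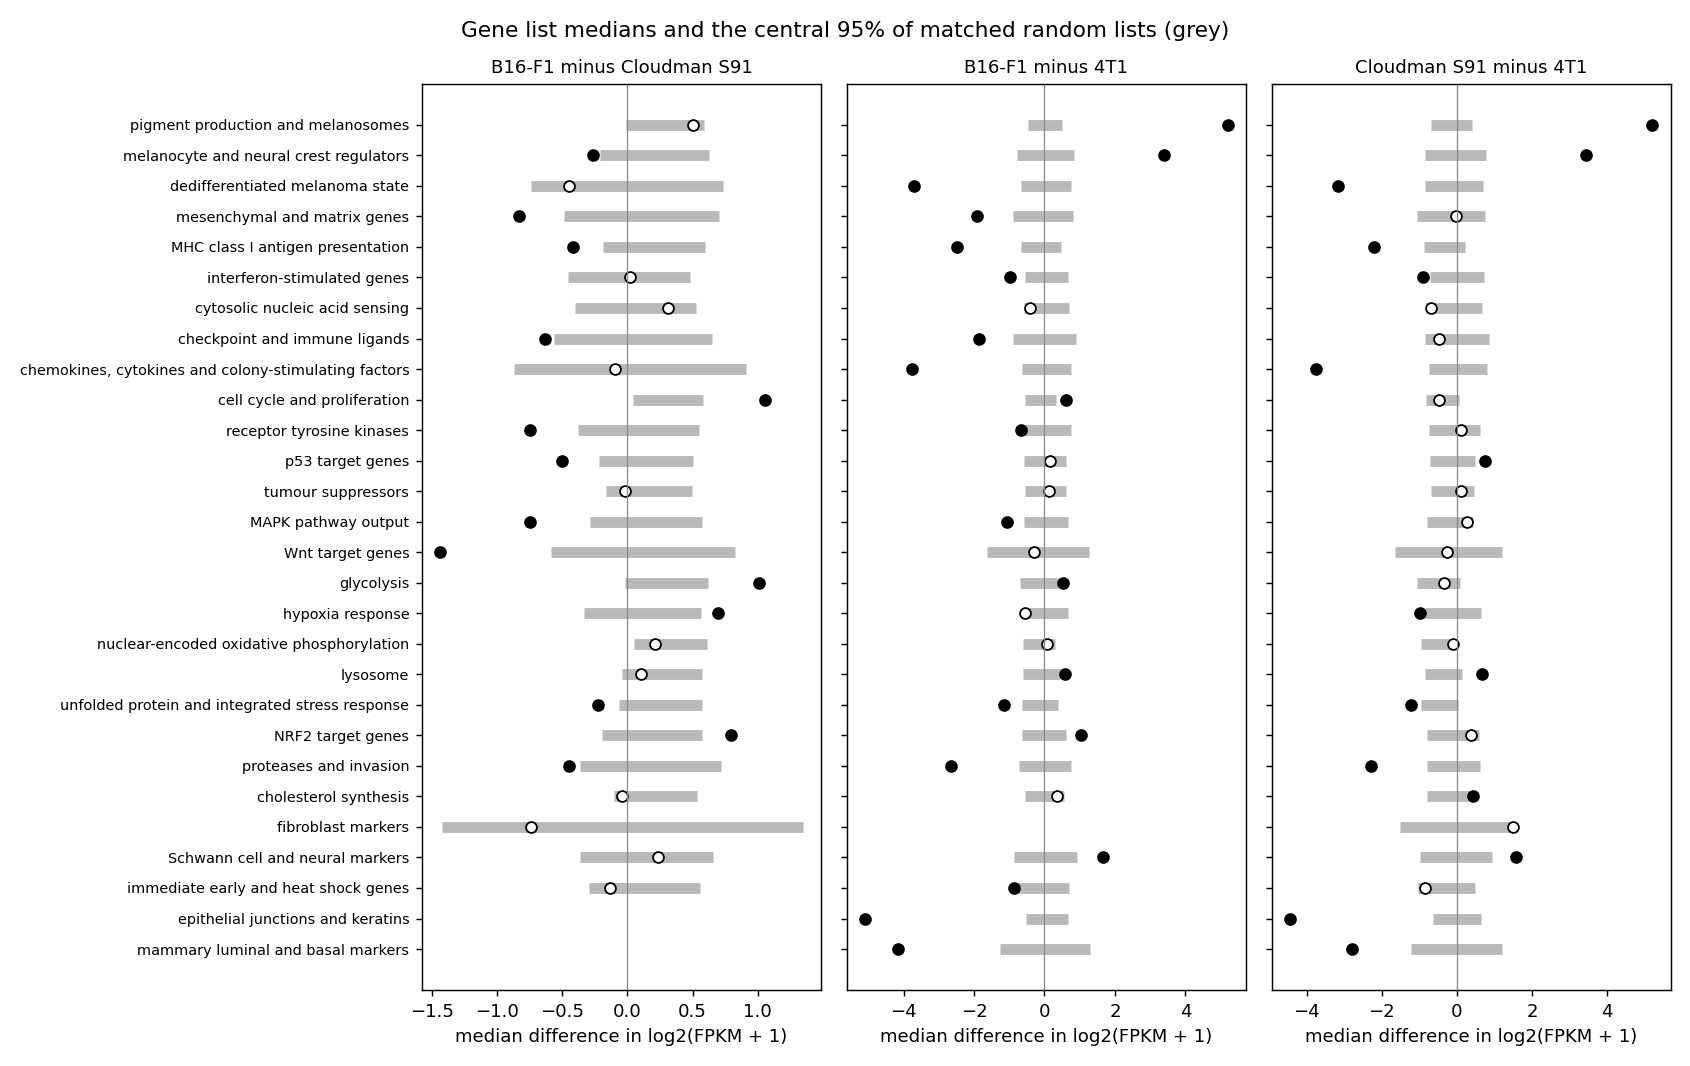
Median difference in log2(FPKM + 1) of each gene list with at least 5 measured members, for the 3 pairs of lines. Grey bars span the central 95% of 10000 matched random lists, filled points lie outside it (pigment genes at 5.20 against 4T1 in both melanoma lines), and the horizontal scales differ between panels.

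Of 10 macrophage markers in the tables, Fcer1g (122) was the only 1 at FPKM 1 or more in Cloudman S91, and Cd68 was at 2.55 in B16-F1 and 11.4 in 4T1. T and NK cell markers were highest for Lck in 4T1 (2.61), endothelial markers for Vwf in Cloudman S91 (11.6), fibroblast markers for Pdgfra in Cloudman S91 (15.6), erythroid markers for Hba-a1 in B16-F1 (6.52) and keratinocyte markers for Sfn in 4T1 (21.4). All 3 measured keratinocyte markers, Krt14 (20.7) among them, were over 4-fold higher in 4T1 than in either melanoma line. MHC class II genes reached 47.6 in 4T1 for Cd74, with only 3 of 6 at FPKM 1 or more. Germline-restricted genes reached at most 2.45 (Sycp3, Cloudman S91). No mitochondrially encoded gene was in the tables.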

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

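The test of whole counts was chosen after its result was seen, and the set of genes with no assembled transcript after seeing the data.

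Assembled genes without a symbol, which enter no comparison except the alternative that adds them to a named gene, held expected counts in every library. Almost all of them have a protein description. They took 2.36% of the expected counts in B16-F1 (Wilson 95% interval 2.35% to 2.37%), 2.24% in Cloudman S91 (2.23% to 2.25%) and 4.32% in 4T1 (4.31% to 4.34%). Between 51.2% (4T1) and 64.5% (B16-F1) of these counts were in those whose description held a term for housekeeping proteins, such as ribosomal proteins, the Gapdh enzyme and tubulins. The terms were matched as text, so that for actin also matches words such as interacting, and the shares may be too high. They are given as values, with no explanation tested.

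Among genes highest in Cloudman S91, 7 exceeded FPKM 1000: Gm13710, Prnp, Slc38a6, Adamts13, Sectm1a, Noct and 1810043G02Rik. Together they held 12.9% of its counts, against 1.07% in B16-F1 and 0.571% in 4T1; 6 of the 7 carry an assembled transcript, and Gm13710 and 1810043G02Rik are described as retroviral gag proteins. A shift of all other genes by these few stays open. Leaving the 50 most abundant genes out of TPM moved the genes higher in Cloudman S91 than B16-F1 from 527 to 625, under 1.5 times (the deposited FPKM, another unit, gave 355). The genes higher in B16-F1 stayed at 387. The median over all genes of B16-F1 minus Cloudman S91 moved from 0.06 to -0.09, the direction that such a shift would give. A median move of this size can hardly change a count under a 4-fold rule by 1.5 times, and the 50 genes are more than these 7. A general excess of assembled transcripts stays open: 35.2% of genes highest in Cloudman S91 (Wilson interval 29.6% to 41.2%) carried one, above the 28.0% of all 11133 compared genes, but 41.2% of genes highest in B16-F1 did so too (32.6% to 50.4%). Reads shared between gene models stay open too, since the share of these genes with a count over 0.005 from a whole number (100%) was above that of the other genes at this level (58.3%), but 7 genes are too few to part their intervals, and a retroviral transcript that is abundant in this line was not tested.

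4T1 lay farther from both melanoma lines than they from each other, with 665 genes highest in it. Over genes with no assembled transcript, 429 were still highest in 4T1, against 164 in Cloudman S91. Assembled transcripts of the genes themselves thus do not account for these 429. Unnamed assembled genes can still share reads with such genes: for Eno1b, which has no assembled transcript, an assembled gene described as enolase held FPKM 682 in 4T1. The separate set of assembled transcripts in its table therefore stays open as a part of the cause. Medium, strain and the library itself cannot be told apart from tumour type, because 0 libraries separate them, and a difference between mammary and melanocytic cells stays open and untested.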

How the results depend on the processing

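Of 18 alternatives, 3 were chosen after seeing the data: only genes with no assembled transcript, only genes listed in all 3 tables, and unnamed assembled genes added to the named gene of the same protein, the last once the low Gapdh value of 4T1 was known. No paired analysis was possible because each line has 1 library, and no replicate could be left out. The most abundant transcript per gene was not run, since the tables hold 1 value per gene. Of 1198 list values under an alternative, 1125 kept their side of the range of random lists, 42 moved inside it, 27 moved outside it and 4 turned. A list turned when its percentile passed the middle of the random lists, whether or not it stayed outside the range, so turned calls may be further losses. Of 1648 values of named genes, 283 moved beyond counting error and 2 turned, and of 251 counts, correlations and list totals, 83 moved. A named gene not listed in a library of the pair had no counting interval. Its values could only turn and were otherwise counted as kept, so the share that kept is partly fixed by the rule. The lists outside the range in every alternative that gave a value were 6 of 14 (B16-F1 and Cloudman S91), 14 of 20 (B16-F1 and 4T1) and 11 of 15 (Cloudman S91 and 4T1), and the number outside ranged from 10 to 15, 17 to 21 and 12 to 19. The counts of genes are given in this order: higher in B16-F1 than Cloudman S91 and the reverse, higher in B16-F1 than 4T1 and the reverse, higher in Cloudman S91 than 4T1 and the reverse, highest in B16-F1, Cloudman S91 and 4T1, higher in both melanoma lines than 4T1, and lower in both. With a pseudocount of 0.1 they were 541, 663, 1200, 1338, 1356, 1424, 239, 412, 1012, 788 and 1012, and r was 0.614 and 0.557 for B16-F1 and Cloudman S91 with 4T1. With a pseudocount of 5 they were 60, 113, 305, 396, 327, 400, 38, 80, 304, 177 and 304, and r was 0.766 and 0.740 for B16-F1 and Cloudman S91 with 4T1. With a 2-fold rule they were 1209, 1014, 2140, 2180, 2103, 2627, 516, 619, 1691, 1320 and 1691. With an 8-fold rule they were 93, 162, 344, 463, 429, 452, 42, 116, 340, 223 and 340. Over genes with no assembled transcript they were 166, 232, 432, 568, 539, 606, 67, 164, 429, 266 and 429. With no filter on low values the moved values were 0.823 (r of B16-F1 and 4T1) and 0.8004 (r of Cloudman S91 and 4T1). Over genes at FPKM 5 or more the moved values were 0.612 (r of B16-F1 and 4T1) and 0.558 (r of Cloudman S91 and 4T1). With TPM the moved values were 1188 (higher in B16-F1 than 4T1), 1414 (higher in Cloudman S91 than 4T1) and 775 (higher in both melanoma lines than 4T1). With TPM without the 50 most abundant genes the moved values were 625 (higher in Cloudman S91 than B16-F1), 1171 (higher in B16-F1 than 4T1), 1552 (higher in Cloudman S91 than 4T1), 391 (highest in Cloudman S91) and 806 (higher in both melanoma lines than 4T1). With counts scaled to the library total the moved values were 441 (higher in B16-F1 than Cloudman S91), 1101 (higher in B16-F1 than 4T1), 187 (highest in B16-F1) and 733 (higher in both melanoma lines than 4T1). Over genes listed in all 3 tables the moved values were 170 (higher in B16-F1 than Cloudman S91), 199 (higher in Cloudman S91 than B16-F1), 562 (higher in Cloudman S91 than 4T1), 44 (highest in B16-F1), 116 (highest in Cloudman S91), 406 (highest in 4T1), 406 (lower in both melanoma lines than 4T1) and 0.732 (r of Cloudman S91 and 4T1). TPM put 56.7% of the calls between B16-F1 and 4T1 higher in B16-F1, and 59.9% of those between Cloudman S91 and 4T1 higher in Cloudman S91, against 45.9% and 48.3% in the deposited FPKM; without the 50 most abundant genes the latter was 60.8%. By construction, other fold limits and gene sets change a count, and a fixed pseudocount weighs less on TPM, whose values are larger. The checkpoint ligands between B16-F1 and Cloudman S91 had a median of 0.074 with no filter, -0.040 under TPM and -0.19 under TPM without the 50 most abundant genes. The receptor kinases between B16-F1 and 4T1 had 0.20 over genes with no assembled transcript. Each of these lay on the other side of the middle of the random lists, which does not put it outside their range, and the cause was not tested. With unnamed assembled genes added, Gapdh in Cloudman S91 minus 4T1 was -1.13 and Rpl3 in B16-F1 minus Cloudman S91 was -0.14, by the construction of the sum. Depth was similar in the 3 libraries (9098072, 7412840 and 8968897 expected counts), and counting error is large only for genes with few counts.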

Other observations

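The families, chromosomes and genes described here, the region on chromosome 6, its FPKM limits of 2 and 0.5, the test of strain variants and the other limits of the shuffles were chosen after the values were seen.

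Several gene families differed between the libraries. Of 12 Rhox homeobox genes, which are normally expressed in reproductive tissue, 7 were at FPKM 1 or more in Cloudman S91, 0 in B16-F1 and 2 in 4T1, with Rhox2d at 57.6 and Rhox2f at 35.3 in Cloudman S91. The Rhox2 genes are near-identical and can share reads, so the family sum (204 in Cloudman S91 against 0.25 in B16-F1 and 3.13 in 4T1) is the firmer value. The 6 genes of the Xlr3 and Xlr4 groups summed to 108 in Cloudman S91, 47.4 in B16-F1 and 0.14 in 4T1. Pregnancy-specific glycoproteins went both ways, with Psg23 at 125 in Cloudman S91 against 6.65 in B16-F1 and 11.7 in 4T1, and Psg16 highest in 4T1 (13.8 against 2.53 in B16-F1 and 2.35 in Cloudman S91). Of 23 Hoxa to Hoxd genes, 9 were at FPKM 1 or more in B16-F1, 8 in 4T1 and 1 in Cloudman S91. Calcium-binding S100a genes summed to 7240 in 4T1, against 298 in B16-F1 and 432 in Cloudman S91.

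Medians over the genes of single chromosomes were shifted, and where along a chromosome the shift lies was not examined. Genes of chromosome 6 had a median 0.78 above that of all genes in B16-F1 minus 4T1 (552 genes) and 0.41 above it in B16-F1 minus Cloudman S91 (540 genes), and genes of chromosome 19 lay at -0.53 and -0.59 relative to all genes in B16-F1 and Cloudman S91 minus 4T1. Each of these 4 medians was beyond all 1000 random gene sets matched on expression. Of 20 chromosomes, 13 were beyond them between the melanoma lines, 9 between B16-F1 and 4T1 and 14 between Cloudman S91 and 4T1. Cdkn2b, which lies beside Cdkn2a, was likewise listed only in Cloudman S91 (4.84), while the nearby Mtap was at 92.9 in B16-F1 and 206 in 4T1.

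On proximal chromosome 6, 4 genes in a row that were at FPKM 2 or more in both other libraries were below 0.5 in Cloudman S91: Ppp1r9a, Pon3, Pon2 and Slc25a13 (4902872 to 6217304). Sgce and Peg10 just before them were at 0.24 and 0.55 in Cloudman S91 and not listed in 4T1, while the flanking Casd1 (13.1) and Shfm1 (220.2) were on. The low genes were not a single block. Gng11, farther out, was not listed in Cloudman S91 but at 13.9 in B16-F1 and 23.6 in 4T1. Bet1 (12.4 in Cloudman S91) and Casd1 were on between Gng11 and Sgce. Chance order stays open. At these limits 0.06% of 10000 shuffles of the 142 low genes over 8770 gave a run as long, under the limit of 5%. With 8 pairs of limits at most 0.4% did. With neighbours of the same symbol stem, such as Pon2 and Pon3, counted once, the share was 4.05% at these limits. It was then under 5% for only 3 of the 8 pairs. For FPKM minimums of 1 and 2 the run was of 3 genes here, and the share was 2.05% to 10.8%. For a minimum of 5 the longest run was of only 2 genes, recorded on another chromosome (25.45% to 48.9%). Strain variants that keep reads from aligning stay open too, since the run, which summed to 0.520% of the lower of the other libraries, was picked for its low values. A deletion or shared silencing of the region may also be behind it, and RNA alone leaves both open and untested.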
